A study of Mus musculus with 12 samples.

How the data were processed

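Poly(A)-selected RNA of the liver was measured in 12 libraries from mice bearing pancreatic ductal adenocarcinoma, 3 per group, and each library was placed in its group by the sample titles: isotype, agoCD40, antiIL1R1 and Combo. The columns were matched to the titles by the library names, which call the controls NoTx (no treatment) where the titles say isotype control. The authors deposited a table of estimated (expected) counts per gene and a table of TPM, with 1 column per library. The deposited expected counts are not scaled between libraries and are in part not whole numbers, while every column of the deposited TPM table has the same total. The submitters' processing notes name STAR, RSEM 1.3.1, StringTie 2.2.1, DESeq2 1.28.0, Trim Galore 0.6.7, cutadapt, Picard 3.0.0, SAMtools 1.16.1, bedtools 2.30.0, FastQC 0.12.1 and the GRCm39 build, without the role of each. The file names point to merged salmon output, and which tool made the counts is not given in the sources used here. No genome sequence or coordinates were used, and genes carry the symbols and identifiers of the tables.

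The expected counts were rounded to whole numbers and analysed in R 4.3.3. Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10), which left 15465 of 56748. All 12 libraries went into 1 fit with TMM scaling and a mean per group, and groups were compared with the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05 and no minimum fold. The biological coefficient of variation was 0.291. Total counts ranged from 18681390 to 27118712 per library. CPM in the text use the TMM-scaled totals and are given as mean and SD of 3 libraries, and fold changes carry a standard error derived from the test. For a gene with 0 counts in a group the fold is a bound against a floor of 3 counts over the group, and for 1 to 3 counts the ratio of counts has a 95% counting interval.

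The comparisons were agoCD40, antiIL1R1 and Combo against isotype, Combo against agoCD40, Combo against antiIL1R1, and the interaction, which is the difference between the agonist effect with and without blockade. The groups are shared between these comparisons, so their results are not independent. For cell types, pathways and carried-over tissue, 31 gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and adjustment over the lists of each comparison. The lists with the check list hold 716 genes, of which 711 are in the table, 620 were tested and 4 are in more than 1 list. Counts adjusted over the list alone are given beside those over all genes. The comparisons, tests, lists and alternatives were fixed before the data were examined, except where a choice is said to be later.

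Genes were named by a rule fixed with the tests: the 6 highest and 6 lowest fold changes among genes past the threshold with a mean of at least 1 CPM and no overlap between the libraries of the groups (the interaction without the overlap condition), leaving out predicted genes and immunoglobulin or T-cell receptor segments. To these were added up to 4 members with the smallest p of each list that passed, up to 2 of other lists, the genes Cd40, Il1r1, Il1a, Il1b and Il1rn, and each gene of a comparison with 5 or fewer calls. The text gives a part of the genes that the rule allows, and the counts of named genes also cover genes not given here. Noct in agoCD40 against isotype and the genes of the immunoglobulin shares and of the precursor and erythroblast lists in the closing section are outside the rule and were picked for the text after their values were seen.

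The steps were tested on simulated counts for 15465 genes with the means and library sizes of these libraries, 100 genes changed 2-fold and 100 changed 4-fold. The changed genes had a mean of at least 1 CPM. Genes were drawn independently, with no structure between libraries, so recovery in the real libraries may be lower. Recovered were 33 and 88 for agoCD40 against isotype, 27 and 80 for antiIL1R1 against isotype, 27 and 87 for Combo against agoCD40, and 8 and 61 for the interaction, with 4, 6, 4 and 5 false calls. For agoCD40 against isotype, DESeq2 recovered 95 of the 4-fold genes with 36 false calls and limma 89 with 6. In simulated independent genes camera called the changed list (adjusted p = 2.0e-40) and 0 of 30 unchanged lists, which does not test lists of correlated genes.

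The alternatives were RLE scaling, total-count scaling, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1), a fit of only the groups compared, and leaving out each library. The lists were also tested with an estimated correlation, with fry, with total-count scaling and with the block. After the data were seen, the mitochondrial percent as a covariate and a fit without isotype 2 and antiIL1R1 2 were added. The replicate numbers were checked for pairing: the median correlation of 18 pairs with the same number was -0.0262, against 0.0316 for other numbers, and 2 pairs were above 0.1, so the libraries were not treated as paired. Both of these pairs were of isotype with antiIL1R1, 0.401 for number 1 and 0.406, the highest, for number 2, against 0.0564 for number 3. Pairing of these groups alone was not fitted, and the labels give no cage, day or batch. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.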

Results

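The study measured RNA in the liver of mice bearing pancreatic ductal adenocarcinoma, an age of 12 weeks being given in the design text. CD40 is a receptor of B cells, dendritic cells and macrophages, and an agonist antibody activates it. IL-1R1 is the receptor through which IL-1α and IL-1β signal, and the blocking antibody prevents this. The 12 libraries fell into 4 groups of 3: controls (isotype), the CD40 agonist (agoCD40), IL-1R1 blockade (antiIL1R1) and both antibodies (Combo). The labels describe the controls both as isotype control and as untreated, so whether they received an antibody is not settled here. Total estimated counts per library ranged from 18681390 to 27118712, and 15465 of 56748 listed genes had enough counts to be tested. The median correlation of log2 CPM was 0.965 between libraries of the same group and 0.957 between libraries of different groups. Mitochondrial transcripts took 14.1% of the counts in isotype 2 and 14.8% in antiIL1R1 2, against 6.23% to 12.2% in the other libraries. The same libraries lay lowest on the first principal component (-72.2 and -58.7), which held 27.7% of the variance. No label ties each library to its own animal, so the p-values measure the spread between these libraries. Every fold change below compares 3 libraries with 3 unless the interaction is named.

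The comparison of agoCD40 with isotype asked what the agonist alone changed. Genes of B cells and plasma cells were higher in agoCD40 livers. Ighm (ENSMUSG00000076617), the heavy chain of IgM, rose from 6.98 ± 1.498 to 71.3 ± 29.97 CPM (mean ± SD, n = 3 per group), a log2 fold change of 3.35 ± 0.29 (SE; adjusted p = 0.000543). Jchain (ENSMUSG00000067149), which links IgM or IgA into polymers, rose from 0.484 ± 0.369 to 14.3 ± 4.32 CPM (log2 4.88 ± 0.44; adjusted p = 0.000543). Igkc, the constant part of the kappa light chain, rose by 3.79 ± 0.45 on the log2 scale (adjusted p = 0.0033). Of the 21 tested genes in the B-cell and plasma-cell list, 5 rose, 0 fell and all had a positive fold change, and 19 rose when adjusted over the list alone. The list had a median log2 fold change of 2.34 and rose as a set (camera adjusted p = 1.7e-42; adjusted p = 0.0323 with an estimated correlation). The erythrocyte and blood list also had a positive median, 0.92, with 0 of 14 genes past the threshold and 2 higher when adjusted over the list alone (camera adjusted p = 0.00049; adjusted p = 0.194 with an estimated correlation).

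Camp (ENSMUSG00000038357), an antimicrobial peptide of neutrophil granules, had 0 counts in the isotype libraries and 330 in the agoCD40 libraries, at least 92.6-fold higher against a floor of 3 counts over the group (adjusted p = 0.00605). Of the 15 neutrophil genes 1 rose and 0 fell, 5 rose when adjusted over the list alone, and the median was 0.63, also with Camp at its bound (camera adjusted p = 0.000391; adjusted p = 0.355 with an estimated correlation). Ngp, another granule protein, measured 0.334 ± 0.578 CPM in isotype and 8.67 ± 1.10 CPM in agoCD40 (adjusted p = 0.0533). Pla2g2d, a secreted phospholipase, was at least 50.2-fold higher on the same floor (adjusted p = 0.00467). H2-Eb2, related to class II MHC beta chains, had 1 count in isotype and 158 in agoCD40, a ratio of 133 with a 95% counting interval of 23.5 to 5286 (adjusted p = 0.0107). Il9r, a cytokine receptor, had a ratio of 74.1 with an interval of 20.2 to 616 (adjusted p = 0.0188). These floors and intervals cover counting error only. Of 11 class II presentation genes 1 rose (H2-Oa, log2 3.83 ± 0.79; adjusted p = 0.0489), 0 fell, and 3 rose when adjusted over the list alone, with a median of 0.75 (camera adjusted p = 0.00035; adjusted p = 0.385 with an estimated correlation). The T-cell list (median 0.83), the NK and cytotoxic list (0.67) and the class I presentation list (0.27) passed camera with 0 members past the threshold (adjusted p = 0.000198, 0.00988 and 0.000402). With an estimated correlation their adjusted p were 0.322, 0.363 and 0.363, and adjusted over the list alone 0, 1 and 2 genes rose.

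Kupffer cells are the resident macrophages of the liver. Their scavenger receptor Cd163 (ENSMUSG00000008845) fell from 18.3 ± 3.17 to 2.45 ± 1.65 CPM (log2 -2.89 ± 0.35; adjusted p = 0.00351), and the lectin Clec4f (ENSMUSG00000014542) fell from 117 ± 19.2 to 36.5 ± 7.16 CPM (log2 -1.68 ± 0.23; adjusted p = 0.0063). Of the 19 Kupffer-cell genes 4 fell and 0 rose, and 8 fell when adjusted over the list alone, with a median of -0.60 (camera adjusted p = 9.4e-15; adjusted p = 0.11 with an estimated correlation). Vsig4, a complement receptor, was among them (log2 -1.42 ± 0.27; adjusted p = 0.0295). The liver endothelium list had a median of -0.39 with 0 genes past the threshold (camera adjusted p = 0.00339; adjusted p = 0.673 with an estimated correlation).

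Itih4 and Itih3, inter-alpha-trypsin inhibitor heavy chains secreted by hepatocytes, fell by 1.14 ± 0.20 and 1.34 ± 0.28 on the log2 scale (adjusted p = 0.0201 and 0.0463). They were the 2 of 31 acute-phase genes that fell, 0 rose, and adjusted over the list alone 15 fell and 2 rose. That list had a median of -0.80 and fell as a set (camera adjusted p = 7.0e-17; adjusted p = 0.0323 with an estimated correlation). Atf3 (ENSMUSG00000026628), a stress-induced transcription factor, fell from 43.9 ± 12.98 to 2.89 ± 1.277 CPM (log2 -3.93 ± 0.45; adjusted p = 0.0033). With Herpud1, which takes part in degradation of misfolded proteins (log2 -0.97 ± 0.16; adjusted p = 0.0131), it made up the 2 of 20 unfolded protein and integrated stress response genes that fell. None of that list rose, 4 fell when adjusted over the list alone, and the median was -0.37 (camera adjusted p = 1.5e-05; adjusted p = 0.0323 with an estimated correlation). Outside the lists, the immediate-early genes Fosb and Nr4a1 fell by 5.80 ± 0.97 and 4.39 ± 0.82 (adjusted p = 0.0153 and 0.0295). Rasd1, a small GTPase, and Mfsd2a, a lipid transporter, fell by 4.63 ± 0.80 and 3.21 ± 0.47 (adjusted p = 0.018 and 0.00759).

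Of 25 genes of gluconeogenesis, amino acid and urea metabolism 3 fell and 0 rose: Igfbp1, which binds insulin-like growth factors (log2 -2.79 ± 0.43), the tyrosine aminotransferase Tat (-1.43 ± 0.25) and the gluconeogenic enzyme Pck1 (-1.04 ± 0.20; adjusted p = 0.00992, 0.018 and 0.0362). Their list had a median of -0.30, with 4 genes lower when adjusted over the list alone (camera adjusted p = 0.000289; adjusted p = 0.308 with an estimated correlation). In fatty acid synthesis 1 of 17 genes fell, the lipogenic transcription factor Srebf1 (log2 -0.94 ± 0.18; adjusted p = 0.0295), as it did when adjusted over the list alone, and the median was -0.20 (camera adjusted p = 0.0038; adjusted p = 0.265 with an estimated correlation). The cytochrome P450 gene Cyp2c70 rose from 220 ± 23.7 to 513 ± 9.67 CPM (log2 1.22 ± 0.14; adjusted p = 0.0033), as the only of 31 drug metabolism genes. In that list 2 rose and 1 fell when adjusted over the list alone, and the median was 0.19 (camera adjusted p = 0.00988; adjusted p = 0.559 with an estimated correlation). Ces2b, a carboxylesterase, rose by 5.50 ± 0.88 (adjusted p = 0.0126). The clock gene Per1 fell from 62.1 ± 12.3 to 19.2 ± 6.13 CPM (adjusted p = 0.00632), while its list did not pass (camera adjusted p = 0.172).

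Further lists held no gene past the threshold or did not pass. Genes that IL-1 induces had a median of -0.86, also with Ccl20 at its bound (camera adjusted p = 0.016; adjusted p = 0.308 with an estimated correlation), and adjusted over the list alone 4 fell and 1 rose. Within it Nfkbiz had a log2 fold change of -1.17 ± 0.25 (adjusted p = 0.0559), while the chemokine Ccl20 was at least 22.7-fold higher (adjusted p = 0.0839). The bile duct and carcinoma epithelium list (median 0.60), the exocrine pancreas list (1.11; 3 of its 30 genes tested) and the stellate cell and matrix list (0.01) were above the other genes (camera adjusted p = 0.00622, 0.022 and 0.0368; adjusted p = 0.194, 0.194 and 0.729 with an estimated correlation), with 0 genes past the threshold over the list alone. The remaining 13 lists had camera adjusted p from 0.0543 (interferon-gamma response) to 0.756, among them the CD40 and NF-kB target list (0.515). Of the antibody targets, Cd40 measured 0.409 ± 0.428 CPM in isotype and 1.15 ± 0.480 in agoCD40 (adjusted p = 0.686), and Il1r1 67.3 ± 14.0 and 39.3 ± 8.56 CPM (adjusted p = 0.0935). Il1a, Il1b and Il1rn had log2 fold changes of -1.64, -1.66 and 0.36 (adjusted p = 0.0653, 0.313 and 0.934).

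In this comparison edgeR called 111 genes, 42 higher and 69 lower, and 1576 had an unadjusted p under 0.05 against 773.25 by chance. DESeq2 called 399, limma on log2(TPM + 1) called 35 higher and 24 lower, on log2(TPM + 0.1) 41 and 26, a fit of only these groups 28. Without isotype 3, agoCD40 1 or agoCD40 3 edgeR called 70, 31 and 28. The excess of lower genes was absent without agoCD40 1 (17 higher and 14 lower), agoCD40 2 (52 and 48) or agoCD40 3 (14 and 14). It remained without isotype 1 (35 and 69), isotype 2 (33 and 64) or isotype 3 (32 and 38). Of the 28 genes named for this comparison that passed, 12 did so whichever 1 library was left out (among them Ighm, Igkc, Ighg2c, Jchain, Camp, Pla2g2d, Cd163, Clec4f, Atf3, Per1 and Cyp2c70). Of these named genes 15 no longer passed without agoCD40 1, 14 without agoCD40 3, 6 without agoCD40 2 or isotype 3, 5 without isotype 1 and 4 without isotype 2.

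**Figure D1:**
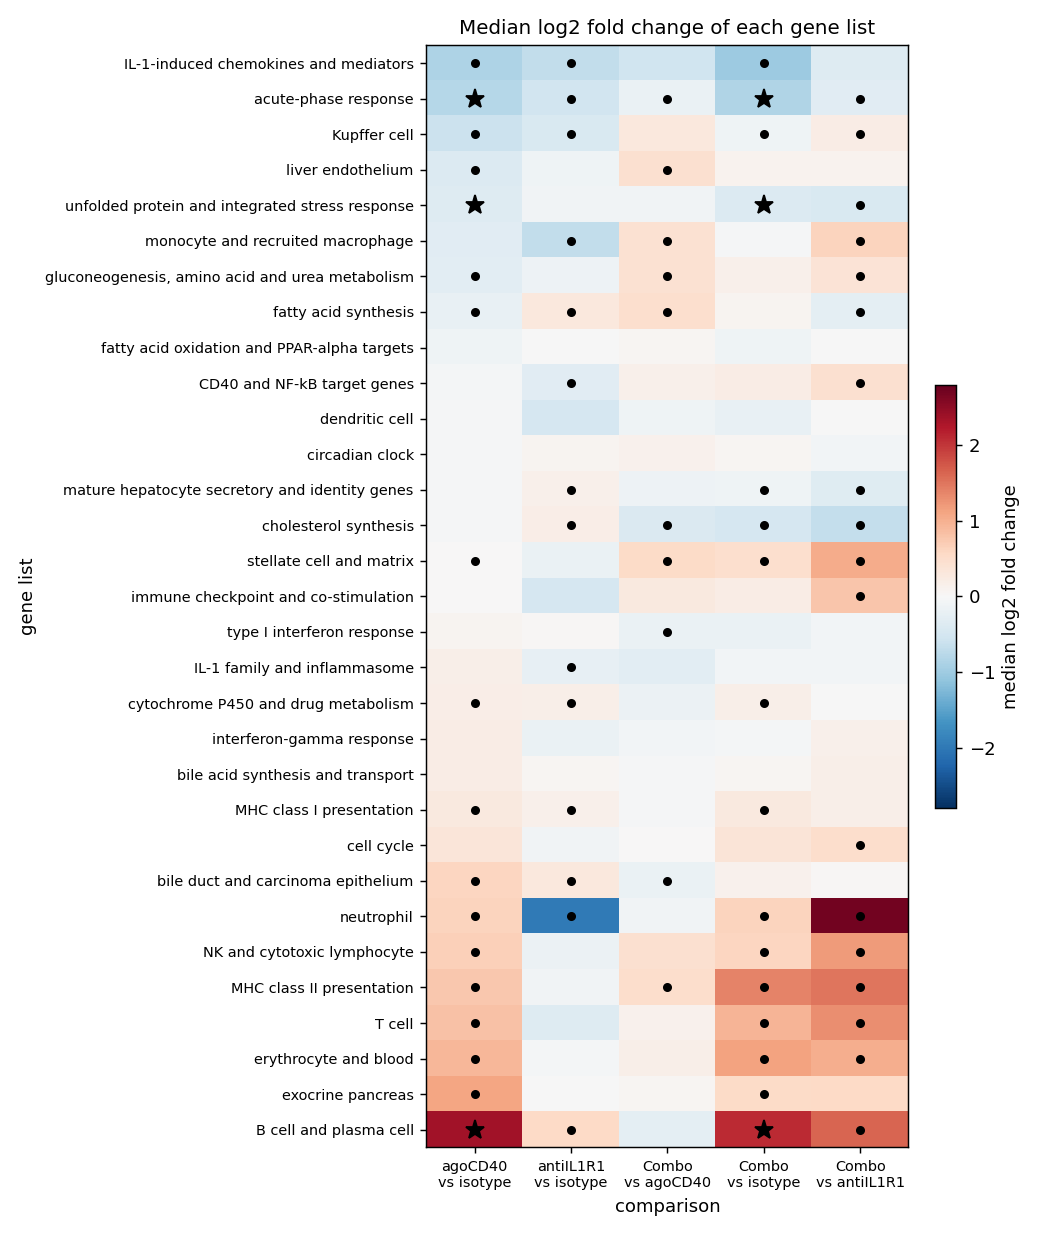
Median log2 fold change (color) of the tested genes of 31 gene lists (vertical axis) in 5 comparisons (horizontal axis), n = 3 libraries per group. Dots mark lists with a camera adjusted p under 0.05 and stars those that also pass with an estimated correlation, which are the B-cell, acute-phase and unfolded protein lists in agoCD40 and in Combo against isotype (medians 2.34, -0.80 and -0.37, and 2.10, -0.84 and -0.38).

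The comparison of antiIL1R1 with isotype asked what the blockade alone changed, and 0 single genes passed over all genes tested. The calprotectin genes S100a8 and S100a9 measured 7.94 ± 3.98 and 9.58 ± 3.96 CPM in isotype against 1.26 ± 0.622 and 2.00 ± 0.964 CPM in antiIL1R1 (log2 -2.66 ± 0.49 and -2.26 ± 0.45, SE; adjusted p = 0.987 for each). Of the 15 neutrophil genes 13 were negative, 0 passed over all genes and 8 fell when adjusted over the list alone. Their median was -1.97, or -1.57 with Ngp, Camp and Mpo, which had 0 counts in a group, at their bounds (camera adjusted p = 7.8e-15; adjusted p = 0.0965 with an estimated correlation). Of the 31 acute-phase genes 27 were negative, 0 passed over all genes and 14 fell when adjusted over the list alone, with a median of -0.53 (camera adjusted p = 1.2e-18; adjusted p = 0.0537 with an estimated correlation). The acute-phase gene Saa1 measured 388 ± 225 CPM in isotype and 121 ± 62.1 in antiIL1R1, the metallothionein Mt2 196 ± 96.6 and 32.0 ± 11.3, and the lipopolysaccharide-binding protein Lbp 116 ± 36.3 and 67.8 ± 3.73.

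Other lists of this comparison passed camera and lost the call with an estimated correlation, and 0 of their genes passed. Monocyte and recruited macrophage genes (median -0.69), Kupffer-cell genes (-0.42), genes that IL-1 induces (-0.68), CD40 and NF-kB targets (-0.33) and the IL-1 family (-0.23) were lower (camera adjusted p = 1.3e-10, 3.3e-05, 0.00069, 0.018 and 0.022; adjusted p = 0.348, 0.392, 0.255, 0.605 and 0.605 with an estimated correlation). Adjusted over each list alone, 0 of these genes passed. Fatty acid synthesis (median 0.30), B-cell and plasma-cell (0.55), cholesterol synthesis (0.18) and mature hepatocyte genes (0.14) were higher (camera adjusted p = 8.2e-07, 1.6e-05, 0.000751 and 0.00676; adjusted p = 0.0965, 0.432, 0.57 and 0.392 with an estimated correlation), with 1, 1, 0 and 0 genes higher when adjusted over the list alone. Within them Mid1ip1, a lipogenic regulator, measured 62.5 ± 6.44 CPM in isotype and 97.5 ± 6.39 in antiIL1R1, and Jchain 0.484 ± 0.369 and 1.69 ± 0.518 (adjusted p = 0.987 for each). Class I presentation (median 0.14), bile duct and carcinoma epithelium (0.31) and drug metabolism genes (0.17, with a mean of -0.01) also passed upward (camera adjusted p = 0.02, 0.02 and 0.0098; adjusted p = 0.648, 0.392 and 0.605 with an estimated correlation), with 0 genes past the threshold over each list alone. The 17 other lists had camera adjusted p from 0.0741 to 0.971. Il1r1, the gene of the blocked receptor, measured 67.3 ± 14.0 CPM in isotype and 41.7 ± 2.86 in antiIL1R1 (log2 -0.69 ± 0.19; adjusted p = 0.987). Il1a, Il1b, Il1rn and Cd40 had log2 fold changes of -0.72, -1.05, -0.63 and -0.59 (adjusted p = 0.987 for each).

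In edgeR 0 of 15465 genes passed and 565 had an unadjusted p under 0.05, fewer than the 773.25 that chance gives, while DESeq2 called 3, limma on either TPM scale 0, and edgeR with no filter on low counts 63. The unadjusted count hung on single libraries, at 1978 without isotype 2, 1077 without antiIL1R1 1 and 355 without isotype 3. In each of these fits 0 genes passed. The libraries with the most mitochondrial counts, isotype 2 and antiIL1R1 2, stand on opposite sides here. In simulated data of this comparison 80 of 100 genes changed 4-fold and 27 of 100 changed 2-fold were recovered. The simulation held independent genes and no structure between libraries, so recovery in these libraries may be lower.

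The comparison of Combo with agoCD40 asked what the blockade added to the agonist. Noct (ENSMUSG00000023087), nocturnin, a rhythmically expressed phosphatase, was the only gene called and rose from 17.4 ± 4.83 to 122 ± 39.9 CPM (log2 2.81 ± 0.34, SE; adjusted p = 0.0301). It measured 106 ± 40.7 CPM in isotype and 114 ± 25.4 CPM in antiIL1R1 livers, and in agoCD40 against isotype it fell by 2.61 ± 0.34 (adjusted p = 0.00467). Cholesterol synthesis genes had lower values in Combo, with 20 of 24 negative, 0 past the threshold over all genes, 10 lower when adjusted over the list alone and a median of -0.41 (camera adjusted p = 3.0e-13; adjusted p = 0.222 with an estimated correlation). Hmgcs1, the HMG-CoA synthase, measured 544 ± 271 CPM in agoCD40 and 169 ± 23 in Combo (adjusted p = 0.158), and the sterol demethylase Cyp51 215 ± 75.7 and 98.2 ± 26.6 (adjusted p = 0.304).

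Of 25 gluconeogenesis, amino acid and urea genes 22 were positive, 0 passed, and 3 rose when adjusted over the list alone (median 0.43). Of 17 fatty acid synthesis genes 13 were positive, 0 passed, and 2 rose when adjusted over the list alone (median 0.48). The camera adjusted p of these lists were 3.0e-09 and 7.8e-06, with adjusted p = 0.222 for both with an estimated correlation. Tat measured 862 ± 114 CPM in agoCD40 and 2337 ± 80.3 in Combo (adjusted p = 0.118), Igfbp1 73.2 ± 16.5 and 305 ± 135 (adjusted p = 0.179), and Srebf1 224 ± 29.0 and 455 ± 66.8 (adjusted p = 0.121). Liver endothelium (median 0.45), monocyte and recruited macrophage (0.42), stellate cell and matrix (0.53) and class II presentation genes (0.48) were higher as sets (camera adjusted p = 3.4e-05, 0.000405, 0.000405 and 0.0155; adjusted p = 0.674, 0.674, 0.674 and 0.719 with an estimated correlation). Type I interferon (median -0.20), bile duct and carcinoma epithelium (-0.18) and acute-phase genes (-0.19) were lower as sets (camera adjusted p = 0.000591, 0.0208 and 0.035; adjusted p = 0.674, 0.475 and 0.674 with an estimated correlation). In these 7 lists 0 genes passed, adjusted over all genes or over the list alone. The other 21 lists had camera adjusted p from 0.0524 to 0.976, the B-cell and plasma-cell list 0.177 with a median of -0.27 and the neutrophil list 0.976. Il1r1, Cd40, Il1a, Il1b and Il1rn had log2 fold changes of -0.30, -0.54, 0.57, 0.74 and 0.20 (adjusted p = 0.815, 0.936, 0.816, 0.872 and 0.97).

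In edgeR 1 gene passed and 960 had an unadjusted p under 0.05, while DESeq2 called 86, limma on either TPM scale 1 and edgeR with no filter 197. Without agoCD40 1, 2 or 3 or Combo 2 or 3 the count was 0, without Combo 1 it was 4. The same agoCD40 libraries served in the comparison with isotype.

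The comparison of Combo with isotype asked what both antibodies changed together. B-cell and plasma-cell genes were again higher. Jchain rose by 5.10 ± 0.45 on the log2 scale, Ighm by 3.08 ± 0.29 and Igkc by 3.83 ± 0.45 (SE; adjusted p = 0.000679, 0.000679 and 0.00261). Ighg2c, the constant region of an IgG subclass, rose from 0.146 ± 0.222 to 16.9 ± 5.64 CPM (SD, n = 3; adjusted p = 0.00261), and Iglc1, a lambda light chain constant region, by 4.85 ± 0.80 (adjusted p = 0.0237). Of the list's 21 genes 4 rose and 0 fell, 17 rose when adjusted over the list alone, and the median was 2.10 (camera adjusted p = 5.4e-34; adjusted p = 0.0297 with an estimated correlation). The erythrocyte and blood list had a median of 1.12 with 0 genes past the threshold and 2 higher over the list alone (camera adjusted p = 3.3e-06; adjusted p = 0.103 with an estimated correlation). Camp was at least 70.3-fold and Pla2g2d at least 56.4-fold higher than in isotype, whose libraries had 0 counts of either (adjusted p = 0.0124 and 0.00468). Gpnmb, a glycoprotein of lipid-associated macrophages, rose from 0.170 ± 0.213 to 7.32 ± 4.46 CPM (adjusted p = 0.0351), while its list of monocyte and recruited macrophage genes did not pass (camera adjusted p = 0.0892).

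In Combo against isotype livers the Kupffer-cell gene Cd163 fell from 18.3 ± 3.17 to 1.23 ± 0.0725 CPM (log2 -3.89 ± 0.38; adjusted p = 0.000711), Clec4f by 2.18 ± 0.23 on the log2 scale (adjusted p = 0.00144) and the folate receptor Folr2 by 1.43 ± 0.22 (adjusted p = 0.0216). Of the 19 Kupffer-cell genes 7 were positive, 4 fell, 0 rose and 6 fell when adjusted over the list alone, with a median of -0.12 (camera adjusted p = 3.4e-08; adjusted p = 0.181 with an estimated correlation). Of the 10 genes that IL-1 induces 3 fell: the neutrophil chemokine Cxcl1 (ENSMUSG00000029380; 32.2 ± 9.78 to 5.08 ± 3.12 CPM; adjusted p = 0.0264), the monocyte chemokine Ccl2 (log2 -3.34 ± 0.64; adjusted p = 0.0473) and Nfkbiz, an inducible NF-kB regulator (-1.55 ± 0.25; adjusted p = 0.0237). None rose over all genes, 5 fell and 1 rose when adjusted over the list alone, and the median was -1.03, also with Ccl20 at its bound (camera adjusted p = 0.000159; adjusted p = 0.154 with an estimated correlation). Of 31 acute-phase genes 4 fell, 0 rose, and adjusted over the list alone 21 fell and 1 rose, with a median of -0.84 (camera adjusted p = 2.8e-24; adjusted p = 0.0277 with an estimated correlation). The fibrinogen genes Fgb and Fgg fell by 1.05 ± 0.16 and 0.96 ± 0.17 and Itih4 by 1.12 ± 0.20 (adjusted p = 0.0203, 0.0358 and 0.0359). Fgl1, a fibrinogen-like protein of hepatocytes, fell by 2.48 ± 0.42 (adjusted p = 0.0258). Il1r1 fell from 67.3 ± 14.0 to 31.9 ± 2.11 CPM (log2 -1.08 ± 0.19; adjusted p = 0.0312), the only call for an antibody target or IL-1 ligand in any comparison. That call was lost on leaving out 5 of the 6 libraries 1 at a time. It was also lost with the replicate block, without isotype 2 and antiIL1R1 2, with limma on either TPM scale and with only the groups compared.

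Among the other lists of this comparison, cholesterol synthesis genes had a median of -0.46 with 22 of 24 negative, 0 past the threshold over all genes and 10 lower over the list alone (camera adjusted p = 3.2e-11; adjusted p = 0.158 with an estimated correlation). The unfolded protein and integrated stress response list fell as a set with a median of -0.38, with 0 of 20 genes past the threshold and 2 lower when adjusted over the list alone (camera adjusted p = 4.5e-06; adjusted p = 0.0297 with an estimated correlation). Class II presentation genes had a median of 1.38 with 0 of 11 past the threshold and 7 higher over the list alone (camera adjusted p = 3.4e-09; adjusted p = 0.181 with an estimated correlation). Cd74, the class II invariant chain, measured 130 ± 74.1 CPM in isotype and 344 ± 90.8 in Combo (adjusted p = 0.176). Stellate cell and matrix genes had a median of 0.47 with 5 of 23 higher over the list alone (camera adjusted p = 4.7e-07; adjusted p = 0.374 with an estimated correlation). The collagen gene Col1a1 measured 7.47 ± 5.65 and 62.2 ± 54.1 CPM (adjusted p = 0.0837). T-cell (median 0.95), neutrophil (0.63, also with Camp at its bound), NK and cytotoxic (0.59) and class I presentation genes (0.28) were higher (camera adjusted p = 1.5e-05, 0.000473, 0.00121 and 0.000608; adjusted p = 0.238, 0.374, 0.238 and 0.396 with an estimated correlation), with 0, 4, 3 and 3 genes higher over the list alone and Camp the 1 gene past the threshold over all genes. Drug metabolism (0.15, with Cyp2c70 rising by 1.04 ± 0.14, adjusted p = 0.0101), exocrine pancreas (0.53) and mature hepatocyte genes (-0.12) also passed camera (adjusted p = 0.0222, 0.0474 and 0.039; adjusted p = 0.615, 0.181 and 0.42 with an estimated correlation). The other 15 lists had camera adjusted p from 0.0892 to 0.937. Cd40, Il1a, Il1b and Il1rn had log2 fold changes of 0.90, -1.07, -0.92 and 0.56 (adjusted p = 0.76, 0.255, 0.581 and 0.78).

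In edgeR 63 genes passed, 39 higher and 24 lower, and 1777 had an unadjusted p under 0.05. With total-count scaling, which moved the median of all genes to 0.11, the split was 52 higher and 10 lower, limma gave 48 and 11 on log2(TPM + 1) and 52 and 9 on log2(TPM + 0.1), a fit of only these groups called 9, and DESeq2 377. Without Combo 1, 2 or 3 edgeR called 12, 16 and 25, and without isotype 1, 2 or 3 it called 24, 38 and 40. The excess of higher genes was absent without isotype 1 (12 higher and 12 lower). It was also absent without isotype 2 and antiIL1R1 2 (17 and 18), a fit chosen after the data were seen. Of the 21 genes named for this comparison that passed, 8 did so whichever 1 library was left out (Ighm, Igkc, Ighg2c, Jchain, Camp, Pla2g2d, Cd163 and Clec4f). Of these named genes 12, 13 and 11 no longer passed without Combo 1, 2 and 3, and 8, 6 and 5 without isotype 1, 2 and 3. The isotype libraries are those of the preceding comparisons with isotype.

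The comparison of Combo with antiIL1R1 asked what the agonist changed under blockade. Ighm rose by 2.51 ± 0.28 on the log2 scale, Jchain by 3.30 ± 0.39, Igkc by 2.93 ± 0.43 and Ighg2b by 4.13 ± 0.48 (SE; adjusted p = 0.00329, 0.00333, 0.0185 and 0.00333). Ighg2c had 1 count in antiIL1R1 and 1226 in Combo, a ratio of 1213 with a counting interval of 217 to 47936 (adjusted p = 0.00306). Of the 21 B-cell and plasma-cell genes 3 rose, 0 fell and 15 rose when adjusted over the list alone, with a median of 1.62 (camera adjusted p = 1.8e-17; adjusted p = 0.112 with an estimated correlation). Of the 15 neutrophil genes 4 rose, 0 fell and 10 rose when adjusted over the list alone, with a median of 2.70, also with Ngp and Mpo at their bounds (camera adjusted p = 2.0e-16; adjusted p = 0.112 with an estimated correlation). Ngp was at least 227-fold higher, Camp had a ratio of 230 with a counting interval of 41.0 to 9141, and S100a8 rose from 1.26 ± 0.622 to 12.4 ± 5.86 CPM (adjusted p = 0.0245, 0.0185 and 0.0218). Pla2g2d had a ratio of 92.5 with an interval of 25.2 to 769 (adjusted p = 0.0125), and Gpnmb rose by 6.17 ± 1.01 (adjusted p = 0.0306). It was the 1 of 25 monocyte and recruited macrophage genes past the threshold, with 9 higher over the list alone and a median of 0.62 (camera adjusted p = 3.8e-09; adjusted p = 0.225 with an estimated correlation).

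Among the 7 genes lower in Combo than in antiIL1R1 livers, Cd163 fell by 3.62 ± 0.37, Clec4f by 1.79 ± 0.23 and Cxcl1 by 2.92 ± 0.46 on the log2 scale (adjusted p = 0.00306, 0.00788 and 0.0245). Cd163 and Clec4f were the 2 of 19 Kupffer-cell genes that fell, and Cxcl1 the 1 of 10 genes that IL-1 induces. In the Kupffer-cell list 10 genes were positive and 0 rose, adjusted over the list alone 7 fell and 1 rose, and the median was 0.22 while the mean was -0.32 and camera pointed down (adjusted p = 0.0243; adjusted p = 0.594 with an estimated correlation). Lanosterol synthase, Lss, fell from 92.6 ± 6.04 to 41.5 ± 2.40 CPM (adjusted p = 0.0243). It was 1 of 24 cholesterol synthesis genes, 15 of which fell when adjusted over the list alone, with a median of -0.67 (camera adjusted p = 1.8e-17; adjusted p = 0.112 with an estimated correlation). Pltp, which transfers phospholipids between lipoproteins, fell by 1.55 ± 0.27 and Glt28d2, a glycosyltransferase homolog, by 1.38 ± 0.21 (adjusted p = 0.0424 and 0.0234).

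Further lists passed camera with 0 genes past the threshold over all genes. Class II presentation (median 1.503), T-cell (1.31), NK and cytotoxic (1.19), stellate cell and matrix (1.05), erythrocyte and blood (1.02) and checkpoint genes (0.78) were higher (camera adjusted p = 1.9e-09, 1.7e-07, 0.0017, 1.0e-07, 0.000135 and 0.0141; adjusted p = 0.177, 0.177, 0.267, 0.295, 0.164 and 0.164 with an estimated correlation), with 8, 3, 2, 7, 0 and 0 genes higher over the list alone. Cell cycle (0.49), CD40 and NF-kB target (0.46) and gluconeogenesis, amino acid and urea genes (0.38) were also higher (camera adjusted p = 0.0243, 0.00706 and 0.0359; adjusted p = 0.594, 0.436 and 0.567 with an estimated correlation), with 0, 1 and 0 genes higher over the list alone. Mature hepatocyte (-0.34), unfolded protein and integrated stress response (-0.42), acute-phase (-0.32) and fatty acid synthesis genes (-0.26) were lower (camera adjusted p = 9.6e-05, 0.00068, 0.00115 and 0.0189; adjusted p = 0.164, 0.112, 0.269 and 0.269 with an estimated correlation), with 0, 2, 4 and 0 genes lower over the list alone. Alb, albumin, measured 57900 ± 2351 CPM in antiIL1R1 and 39360 ± 1849 in Combo (adjusted p = 0.185). The other 13 lists had camera adjusted p from 0.0842 to 0.958. Il1r1, Cd40, Il1a, Il1b and Il1rn had log2 fold changes of -0.39, 1.49, -0.35, 0.13 and 1.18 (adjusted p = 0.349, 0.461, 0.653, 0.931 and 0.377).

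In edgeR 27 genes passed, 20 higher and 7 lower, and 2373 had an unadjusted p under 0.05. With total-count scaling, which moved the median of all genes to 0.19, the split was 32 higher and 5 lower, limma gave 42 and 4 on log2(TPM + 1) and 40 and 4 on log2(TPM + 0.1), DESeq2 called 486, and a fit of only these groups 65. Without antiIL1R1 1, 2 or 3 edgeR called 16, 6 and 4, and without Combo 1 or 2 it called 12 and 9. Without isotype 2 and antiIL1R1 2, a choice made after the data were seen, 9 genes passed here, 35 in Combo against isotype and 87 in agoCD40 against isotype. Of the 16 genes named for this comparison that passed, Cd163, Ighg2c and Ighm did so whichever 1 library was left out. Of these named genes 6, 11 and 13 no longer passed without antiIL1R1 1, 2 and 3, and 7, 9 and 2 without Combo 1, 2 and 3. The Combo and antiIL1R1 libraries also served in the comparisons above, while none is shared with agoCD40 against isotype.

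**Figure D2:**
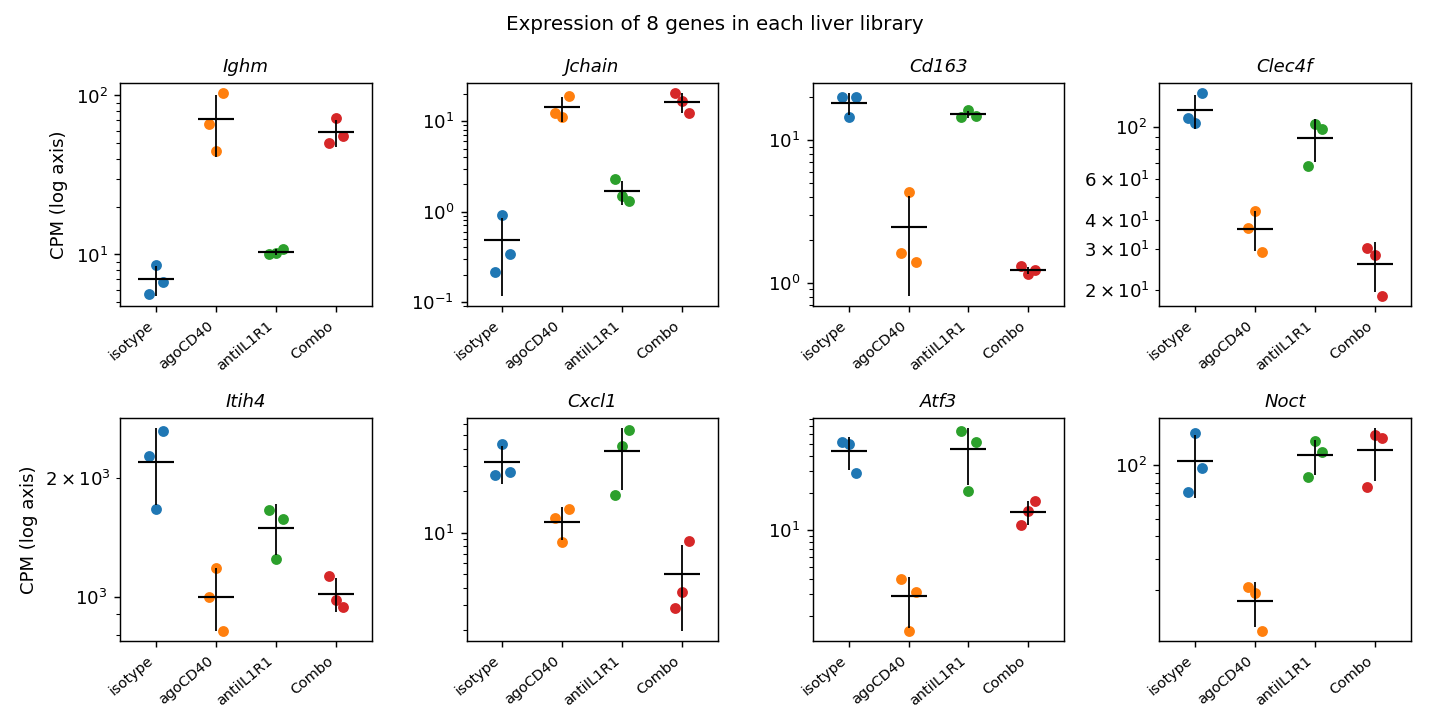
Expression of 8 genes in CPM (vertical axes, logarithmic) in each of the 12 libraries by treatment group (horizontal axes); each dot is 1 library, and bars give the mean and SD of the 3 libraries of a group, the lower bar ending no lower than 0.5 times the smallest value. Mean Cd163 was 18.3, 2.45, 15.2 and 1.23 CPM and mean Noct 106, 17.4, 114 and 122 CPM in isotype, agoCD40, antiIL1R1 and Combo.

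The interaction test asked whether the effect of the agonist differed with and without blockade, over all 4 groups. Ddit4 (ENSMUSG00000020108), a stress-induced inhibitor of mTOR signalling, was the only gene called, with a log2 difference of 4.13 ± 0.52 (SE; adjusted p = 0.0422). It measured 27.6 ± 11.7 CPM in isotype, 5.24 ± 1.275 in agoCD40, 7.30 ± 1.90 in antiIL1R1 and 24.3 ± 11.2 in Combo. Genes of monocytes and recruited macrophages had a median difference of 1.03 with 24 of 25 positive, and neutrophil genes of 2.12, or 1.84 with Ngp, Camp and Mpo at their bounds (camera adjusted p = 4.7e-10 and 1.3e-06; adjusted p = 0.389 for both with an estimated correlation). Cholesterol synthesis genes had a median of -0.62 with 21 of 24 negative (camera adjusted p = 4.5e-12; adjusted p = 0.389 with an estimated correlation). Adjusted over the list alone 4, 3 and 11 genes of these lists passed, all in the direction of their list.

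Of the remaining lists, gluconeogenesis, amino acid and urea (median 0.64), Kupffer-cell (0.56), acute-phase (0.47), endothelium (0.48), stellate cell and matrix (0.90) and class II genes (0.67) had positive differences (camera adjusted p = 1.3e-06, 0.000337, 0.000726, 0.00257, 0.00257 and 0.0427; adjusted p = 0.389, 0.516, 0.394, 0.853, 0.853 and 0.853 with an estimated correlation). B-cell and plasma-cell (-0.75), bile duct and carcinoma epithelium (-0.64), mature hepatocyte (-0.26) and type I interferon genes (-0.20) had negative differences (camera adjusted p = 0.000337, 0.00257, 0.00467 and 0.0413; adjusted p = 0.641, 0.389, 0.394 and 0.853 with an estimated correlation). No gene of these lists passed over all genes, and adjusted over the list alone 2 gluconeogenesis and 3 Kupffer-cell genes did, all positive. Per1 had a difference of 2.02 ± 0.33 (adjusted p = 0.104), Igfbp1 of 3.20 ± 0.58 (adjusted p = 0.123) and Tat of 1.88 ± 0.34 (adjusted p = 0.126). The 18 other lists had camera adjusted p from 0.0615 to 0.921. Il1r1, Cd40, Il1a, Il1b and Il1rn had differences of 0.39, 0.05, 1.29, 1.79 and 0.83 (adjusted p = 0.745, 0.993, 0.636, 0.665 and 0.808).

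In edgeR 1 gene passed and 1161 had an unadjusted p under 0.05, while DESeq2 called 87, edgeR with no filter 232, and edgeR with total-count scaling, which moved the median of all genes to 0.13, and limma on either TPM scale 0. Without isotype 1 the count of genes past the threshold was 13, and it was 0 without isotype 3, Combo 1 or 2, or any agoCD40 or antiIL1R1 library. The unadjusted count ranged from 669 without isotype 3 to 2703 without isotype 2. In simulated independent genes, with no structure between libraries, 61 of 100 interactions of 4-fold and 8 of 100 of 2-fold were recovered.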

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

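The immediate-early, glucocorticoid, stroma and erythroblast lists were picked to follow up patterns already seen, with bounds written before their own values were read. The tests of the agonist effect under blockade, of blood and of mature neutrophils were chosen only after the result was seen.

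The interaction test called 1 gene, a difference in the agonist effect between livers with and without IL-1R1 blockade. That gene was Ddit4, with a log2 difference of 4.13 ± 0.52 (adjusted p = 0.0422). In redrawn groupings, 11 of 100 draws, the real one included, gave at least 1 gene, so chance is not excluded. The draws moved libraries across all 4 groups and did not keep the effects of each antibody. Their share is thus not a chance level for the interaction alone. The highest other draw gave 2178 genes against 1. It set the libraries with 6.23 to 9.11% mitochondrial counts against those with 9.89 to 14.8%. This points to a structure of the samples that goes with the mitochondrial percent, and its cause was not tested.

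The first pattern is the 69 genes lower in agoCD40 than in isotype livers. Their excess over the 42 higher genes was absent when any 1 of the agoCD40 libraries was left out. Immediate-early genes on a separate list, picked after Fosb and Nr4a1 were seen to fall, had a median of -1.16. Of these, 18 of 20 were negative and 0 passed the threshold. Glucocorticoid-induced genes that were not called had a median of -1.10 with 7 of 10 negative. In Combo against antiIL1R1 the medians of these lists were -0.03 (11 of 20 negative) and 0.31 (3 of 10 negative). Because the lists follow up falls already seen in the same libraries, they are no independent support for a cause. A difference in stress or timing at tissue collection may contribute, and an effect of the agonist on the same genes stays open. The fall of the 69 genes was smaller under blockade. Their median log2 fold change was -0.39 in antiIL1R1 and -0.67 in Combo against isotype, and -0.21 in Combo against antiIL1R1. A lower start in antiIL1R1 may thus account for part of the smaller fall. The isotype libraries took part in choosing the 69 genes, which can lower both medians against isotype. Genes chosen without 1 agoCD40 and 1 isotype library changed by -1.42 ± 0.16 in those libraries. They changed by -0.37 ± 0.13 in Combo against antiIL1R1, a ratio of 0.259. A ratio of at least 0.5 was needed for an agonist effect independent of blockade, a bar set after the result was seen. The gap to that bar was 0.341 ± 0.156 with 3 libraries per group, so such an effect is not settled for the set as a whole. Higher genes chosen in the same way changed by 2.25 ± 0.246 and 2.10 ± 0.0174, a ratio of 0.931. The set of lower genes is mixed, with 46 of the 69 in the same direction under blockade. Cd163 and Clec4f were called in both comparisons (log2 -2.89 and -1.68 without, -3.62 and -1.79 with blockade). Collection order and time are not in the labels, so the collection was not tested apart from the treatment.

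The second pattern is the higher B-cell and plasma-cell genes in agoCD40 and Combo. More blood in the liver cannot be told apart from it, since the rise of the list exceeded that of the globin genes by 1.22 ± 1.297 in agoCD40 and 0.348 ± 0.772 in Combo. Carried-over lymphoid tissue stays open as well, with a median of 0.566 for stroma genes of which 4 of 7 were tested (score 0.576 ± 0.459). An effect of the agonist on B cells in the liver may be the source, and no test here separates these.

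The third pattern is the higher granulocyte-precursor genes (median 3.95 in agoCD40 and 3.75 in Combo against isotype, 7 of 10 tested), of which 1, Camp, passed the threshold in each comparison, while Prtn3 went from 1018 counts in isotype to 277 in agoCD40. Against isotype the mature score did not rise, at -0.84 ± 0.26 in agoCD40 and -0.80 ± 0.55 in Combo. This argues against more mature neutrophils as the whole cause. Its distance from the precursor score (-3.74 ± 0.23 and -3.56 ± 0.34) is in part fixed in advance, since that list holds Camp and Ngp, already seen to rise. Against antiIL1R1, 5 of 7 mature genes were positive in Combo (score 0.797 ± 0.659). More blood stays open, with the globin score changed by 1.05 ± 0.894 in agoCD40 and 1.74 ± 0.709 in Combo. Carried-over bone marrow may also be the source and cannot be told apart. Its test rested on Epor and Sptb, the 2 of 9 erythroblast genes with enough counts (median -0.59), and the bound set for it beforehand was found wrong after the value was seen, because isotype livers already held 111 and 156 counts of them. Precursors forming in or entering the liver were not tested.

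For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split gave 111 genes for agoCD40 against isotype (highest other 0; 1 split as high), 1 for Combo against agoCD40 (0; 1 split), 63 for Combo against isotype (1; 1 split) and 27 for Combo against antiIL1R1 (0; 1 split). For antiIL1R1 against isotype edgeR gave 0 (565 at unadjusted p under 0.05; DESeq2 3, limma 0) and each of the 10 splits gave at least as many. On leaving out 1 library the 565 ranged from 355 without isotype 3 to 1978 without isotype 2. The highest other gave 2782, with isotype 2, antiIL1R1 2 and antiIL1R1 3 on 1 side, which points to a structure of the samples. Of the libraries compared, these held the most mitochondrial counts (14.1, 14.8 and 10.9%). They also lay lowest of all libraries on the first principal component (-72.2, -58.7 and -34.3). This structure cuts across the treatment groups, and its cause was not tested.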

How the results depend on the processing

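The mitochondrial covariate and the fit without isotype 2 and antiIL1R1 2 were chosen after seeing the data. Counts of genes are given in the order agoCD40, antiIL1R1 and Combo against isotype, Combo against agoCD40, Combo against antiIL1R1 and the interaction, with 111, 0, 63, 1, 27 and 1 as reported, and only counts that moved by over 1.5 times are listed. With no filter, which tests more genes, they were 466, 63, 466, 197, 742 and 232. With DESeq2 they were 399, 3, 377, 86, 486 and 87. The replicate block gave 72 for the first, 23 for Combo against isotype, 2 against agoCD40, 9 against antiIL1R1 and 0 for the interaction. The mitochondrial covariate gave 256, 292 for Combo against isotype, 11 against agoCD40 and 3 for the interaction. Without isotype 2 and antiIL1R1 2, with fewer samples, Combo gave 35 against isotype and 9 against antiIL1R1, and the interaction 0. Limma on log2(TPM + 1) gave 59 for agoCD40 and 46 for Combo against antiIL1R1, on log2(TPM + 0.1) 67 and 44, and 0 for the interaction on both. Only the groups compared, with fewer samples, gave 28 for agoCD40, 9 for Combo against isotype, 2 against agoCD40 and 65 against antiIL1R1. Total-count scaling gave 0 for the interaction. RLE scaling moved no count by that much. Leaving out 1 library gave 28 to 104, 0 to 0, 12 to 40, 0 to 4, 4 to 36 and 0 to 13. The causes of these moves were not tested. With TPM the median of all genes was at most 0.29 (Combo against antiIL1R1, log2(TPM + 0.1)). No named gene or list past the threshold reversed direction. Some values of named genes that did not pass changed sign. These were 1 with the block, 5 with the covariate, 2 without the 2 libraries and 1 on each TPM scale. On leaving out 1 library 14 of 612 did. Of 96 values of named genes, 96 kept direction and side of the threshold with RLE, 84 with total counts, 93 without filter, 94 with DESeq2, 73 and 74 on TPM, 89 with the covariate, 73 without the 2 libraries and 69 with the block, and 57 of 90 with only the groups compared. Over all left-out libraries 430 of 612 did. Of 89 list calls, 84 stayed with total counts, 87 with the block, 6 with an estimated correlation and 21 with fry. Same-number pairs correlated from -0.395 to 0.406, so the pairing check gave no general sign of pairing and excludes none for single pairs. Sets of simulated 2-fold changes were recovered at 33 of 100 for agoCD40 against isotype, which limits what a missing call says.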

Other observations

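The share of Ighg2c in immunoglobulin heavy chain constant region counts was 0.921 ± 1.26% in isotype, 6.38 ± 1.92% in agoCD40, 0.0875 ± 0.152% in antiIL1R1 and 14.4 ± 3.32% in Combo (mean ± SD, n = 3). The share of Ighm was 64.2 ± 12.5%, 67.9 ± 0.704%, 54.2 ± 5.45% and 51.7 ± 8.21%, and that of Igha 10.9 ± 8.33%, 8.29 ± 1.82%, 25.8 ± 8.45% and 15.3 ± 7.54%, in the same order. These shares were not tested.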
